A study of Mus musculus with 8 samples.

How the data were processed

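Total RNA from FoxP3-sorted mouse Tregs of WT and KO-labelled animals was hybridised to 8 Affymetrix arrays, after stimulation through CD3 and CD28 for 16 h and labelling of 100 ng of RNA by the whole-transcript protocol, per the labels' protocols. The labels state that ribosomal RNA was not removed. The deposited values are log2 expression summaries per probe set, made by the authors with RMA in Partek, per the submitters' processing notes. The versions of both tools, and any filter on probe sets, are not given in the sources used here. RMA commonly subtracts background, normalizes between arrays and summarises the probes of a set. The deposited arrays had nearly equal means but SDs of 1.56 to 1.87 log2, and this difference in spread can widen or narrow differences between arrays for whole sets of genes. The values were checked to hold 28768 probe sets on a log2 scale with none missing. The deposited table was used with no further normalization, and scanner files were not used here. All 8 columns were matched to samples, leaving 0 columns of per-sample values unused.

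Groups were taken from the sample titles and genotype labels, as 4 KO-labelled and 4 WT arrays, each with preparations 1 and 2 and letters A and B. No 2 arrays held identical values: the closest pairs were KO 2A with KO 2B and WT 1A with WT 2B, each with a root mean square difference of 0.17 log2.

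Gene names came from the platform annotation, which can be old. Of the probe sets, 21771 had 1 gene symbol, 1557 had several and 5440 had none in that table, and 0 symbols were updated through gene identifiers in a RefSeq gene table of assembly GRCm38.p6. Only probe sets with 1 symbol entered the main test. For the 999 genes with more than 1 probe set, the set with the highest mean over all arrays was used, leaving 19937 genes. No filter on dim probe sets was applied. Genes of the fixed lists with no matching symbol, Xist among them, were not analysed here.

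KO-labelled and WT arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a variance trend). The labelled preparation was a random block through duplicateCorrelation, which estimated a correlation of 0.617 between arrays of a preparation. The moderated test had 12.8 degrees of freedom. The estimate is 1 value for both groups and depended on the KO-labelled arrays. It was 0.875 without WT 1 and 0.752 without WT 2, but -0.63 without KO 1 and -0.64 without KO 2. In WT the block was not borne out: over probe sets WT 1A correlated at 0.968 with WT 1B and at 0.994 with WT 2B. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Errors given as SE are those of the fitted log2 difference, and fold differences are powers of it. The median difference over all genes was -0.06 as deposited, -0.01 after quantile normalization and 0.04 after centring each array on its median, and reported differences can be read against that shift.

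There were 30 gene lists, written from textbook knowledge of T cell subsets, BCL6 and other cell types, and 29 were tested with cameraPR on the moderated statistics with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over lists. Lists with under 3 measured genes were only counted. Beside it, camera estimated the correlation from the 8 arrays in a fit with no block for preparations. It therefore differs from the preset test in the model as well as in the correlation. With the block, fry tested whether the genes of a list move on balance one way, which compares no list with other genes. With the preset correlation 14 lists were higher and 3 lower. With an estimated correlation 0 of these calls held in camera, while 4 lists were higher and 1 lower at an unadjusted p under 0.05. Lists overlap, so their tests are not independent.

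The design, the lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule named Bcl6; the 10 largest rises and 10 largest falls among called genes whose arrays do not overlap, leaving out predicted genes, immunoglobulin and T cell receptor segments and olfactory receptors; up to 4 called members of each list with the smallest p; and Foxp3, Gata3, Prdm1, Il4, Il5, Il13, Il10, Cxcr5, Ccl3, Tbx21 and Irf4 whether called or not; 1 further gene of the rule is not reported here. Other genes are named with a remark, and Fgl2 was named to complete a count. The alternatives were other treatments of preparations, numbers and letters, other variance models, array weights, quantile and median scaling, a filter at log2 6, other choices of probe sets, a test against a 1.2-fold change, and leaving out each array or preparation. After the data were examined, 5 were added: the SD of each array as a covariate, leaving out KO 1 or KO 2 with no random block, leaving out Y-linked genes, and quantile normalization together with preparation means.

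The test was run on simulated data of 19937 genes in 8 arrays of 4 preparations. It recovered 10% of genes changed by 0.5 log2, 52% at 1, 92% at 2 and 100% at 4, and 13 of 140 calls were false (9.29%), above the nominal rate. The simulated correlation of 0.6 between arrays was estimated as 0.523. It was the same in both groups, whereas in the real WT arrays the block was not borne out. The rates of recovery and of false calls may therefore differ for the real arrays. In the simulated list test, 5 of 5 shifted sets were recovered and 0 others called, but every gene of those sets was shifted by more than its own SD. Smaller shifts, or shifts of only some genes of a set, were not tried. Simulated genes were drawn independently of each other. The list test was therefore not tried on lists whose members move together, such as cell cycle genes, with an estimated correlation of 0.831.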

Results

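Gene expression was measured in regulatory T cells (Tregs), the CD4 T cells that restrain immune responses and are marked by the transcription factor FoxP3. The cells came from wild-type (WT) mice and from mice labelled as lacking Bcl6 (KO), a transcriptional repressor of the BTB zinc finger family that directs the follicular helper T cell program. Sorted Tregs had been stimulated through CD3 and CD28 for 16 h, and 100 ng of total RNA was labelled for each Affymetrix whole-transcript array. There were 8 arrays, 4 labelled KO and 4 WT. Each group held preparations 1 and 2, and each preparation an array A and an array B. The labels do not say whether preparations or letters are separate mice, cultures or extracts, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision of every value.

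The arrays differed in spread as well as in level. The SD of log2 values over all probe sets was 1.87 in KO 1A and 1.84 in KO 1B, against 1.65 in KO 2A, 1.61 in KO 2B and 1.56 to 1.70 in the 4 WT arrays. Median log2 expression ranged from 6.80 in KO 1A to 7.13 in KO 2B. A principal component that set the KO 1 arrays apart from WT 1A and WT 2B held 81.3% of the variance. The KO 2 arrays lay among the WT arrays on it, with loadings of -0.11 and -0.16. Those of the WT arrays were -0.39 to 0.02, and those of KO 1A and KO 1B 0.63 and 0.52. Over probe sets the KO 2 arrays correlated with the WT arrays at 0.979 to 0.989 and with the KO 1 arrays at 0.935 to 0.956. This component therefore did not follow the genotype label. The mean of the Y-linked genes Eif2s3y, Kdm5d and Uty separated the groups in all 8 arrays. Usp9y and Zfy1, also Y-linked, differed by only -0.105 and -0.045 log2 between the groups. The mean log2 level of Eif2s3y, Kdm5d and Uty was 4.62 to 4.80 in the KO-labelled arrays and 6.95 to 8.30 in the WT arrays, so the Y-linked level ran along with the genotype label in every result below.

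**Figure D1:**
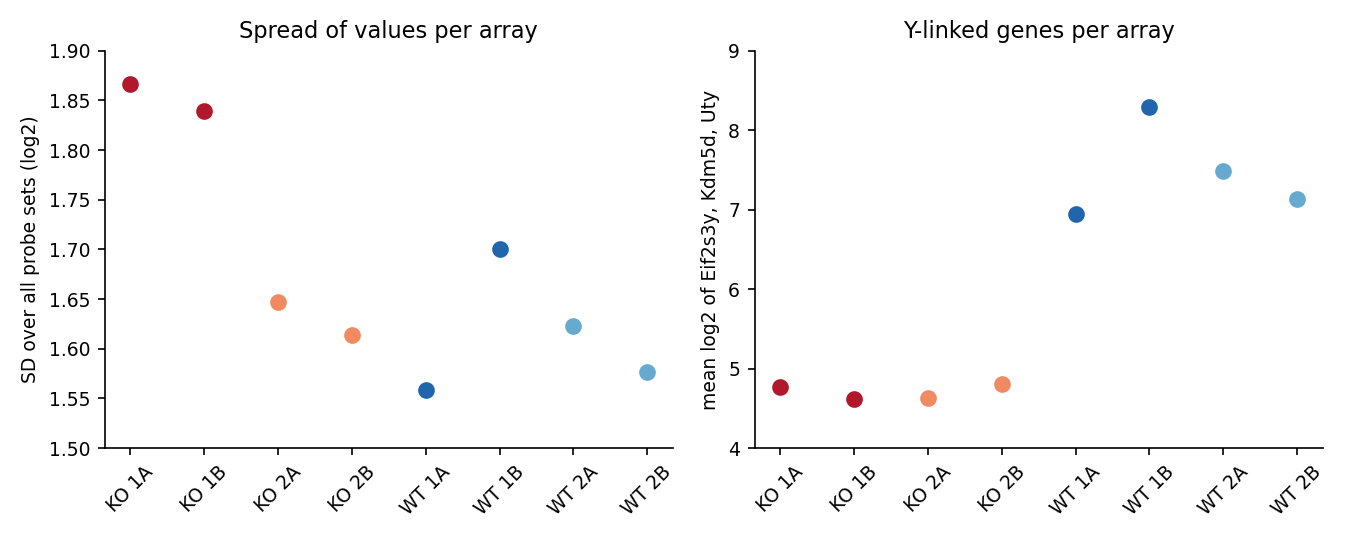
Left, SD of log2 values over all probe sets of each array; right, mean log2 level of the Y-linked genes Eif2s3y, Kdm5d and Uty in each array. Colours mark the preparation. KO 1A and KO 1B have the widest spread, at 1.87 and 1.84, and the 4 KO-labelled arrays lie at 4.62 to 4.80 on the Y-linked genes, below all 4 WT arrays.

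The targeted gene was examined before all others. Bcl6 (probe set 10438738) had a log2 level of 8.72 ± 0.24 (SD, n = 4) in the KO-labelled arrays and 8.13 ± 0.25 (SD, n = 4) in the WT arrays. Each KO-labelled array was above each WT array: the KO-labelled values were 9.0 and 8.82 in preparation 1 and 8.54 and 8.51 in preparation 2, and the WT values 7.97, 8.36, 8.33 and 7.86. The log2 difference was 0.59 (SE 0.29), with an adjusted p of 0.701, and did not pass the test. The labels do not describe which part of the gene was removed, and the place of the probes within the gene was not used here, so this level does not check the labels. The arrays are therefore called KO-labelled throughout.

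The comparison of KO-labelled with WT Tregs asked which genes are expressed at another level when Tregs lack Bcl6, including genes of the Th2 type, those of the helper cells that make Il4, Il5 and Il13. The largest rise was that of Klrg1 (probe set 10547590), a lectin-like receptor of differentiated effector lymphocytes, at 11.15 ± 0.36 against 7.06 ± 0.27 log2 (SD, n = 4 each), a 17.0-fold difference. Penk, which encodes the enkephalin precursor, rose 15-fold, Gzmb, the serine protease granzyme B, 11.6-fold, and Ccr2, a receptor for the chemokine Ccl2, 10.2-fold. Itgae, the alpha E integrin chain CD103, rose 8.43-fold and Id2, an inhibitor of E proteins, 7.05-fold. The folds differed between preparations: Penk was 4.68 log2 above WT in KO 1 and 3.13 in KO 2, Gzmb 4.50 and 2.57, and Id2 3.45 and 2.18. The 3 genes that fell were all Y-linked, namely Eif2s3y, Srsy and Kdm5d.

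With limma and Benjamini-Hochberg adjustment over 19937 genes, 24 genes were higher and 3 lower, and 1235 genes had an unadjusted p under 0.05. In all 27 called genes the KO-labelled and WT arrays did not overlap. Over all genes, 1329 were higher and 421 lower with no overlap, 8.78% of those tested. Chance gives 2.86% for 4 independent arrays against 4 and up to 33.3% where both arrays of a preparation move as one, so this share is not set against chance; the other ways to group whole preparations gave 3.23% and 0.722%. The log2 difference of Klrg1 was 4.09 (SE 0.30) with an adjusted p of 9.4e-05, that of Penk 3.90 (SE 0.39) with 8.2e-04, that of Ccr2 3.35 (SE 0.29) with 3.9e-04 and that of Itgae 3.08 (SE 0.29) with 6.6e-04. Gzmb differed by 3.53 (SE 0.44) and Id2 by 2.82 (SE 0.35), each with an adjusted p of 0.00652. S100a6, a calcium-binding protein, differed by 2.57 (SE 0.31), Ttc39c by 2.5 (SE 0.35) and Cldnd1 by 2.30 (SE 0.36), with adjusted p of 0.00544, 0.0109 and 0.0284; Ttc39c was 3.19 above WT in KO 1 and 1.81 in KO 2. Among the genes that fell, Eif2s3y differed by -3.69 (SE 0.60), Srsy, a multicopy gene, by -3.67 (SE 0.35) and Kdm5d by -2.12 (SE 0.27), with adjusted p of 0.0328, 6.6e-04 and 0.0069. The Cldnd1 call was lost without KO 1B (adjusted p = 0.0521), WT 2A (adjusted p = 0.0604) or WT 2B (adjusted p = 0.0805), and the Eif2s3y call without KO 1B (adjusted p = 0.0606) or WT 2A (adjusted p = 0.0715). Median centring ended the calls of Cldnd1 (adjusted p = 0.117), Eif2s3y (0.0986) and Ttc39c (0.0726), leaving out both WT 1 arrays those of Cldnd1 (0.147) and Ttc39c (0.0796), and a fit with no variance trend that of Eif2s3y (0.0962). A test against a 1.2-fold change did not call Cldnd1 and Eif2s3y (0.0517 each), Gata3 (0.0593) or Cd44 (0.0760). After quantile normalization 121 genes were higher and 36 lower, including all 27 in the same direction, and without preparation WT 2 limma called 0, with 200 genes at an unadjusted p under 0.05. Leaving out 1 array moved the count of higher genes to 14 without KO 1B, 49 without KO 2B, 51 without WT 1B and 13 without either WT 2A or WT 2B, and the count of lower genes to 6 without KO 2B, WT 1A or WT 1B.

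**Figure D2:**
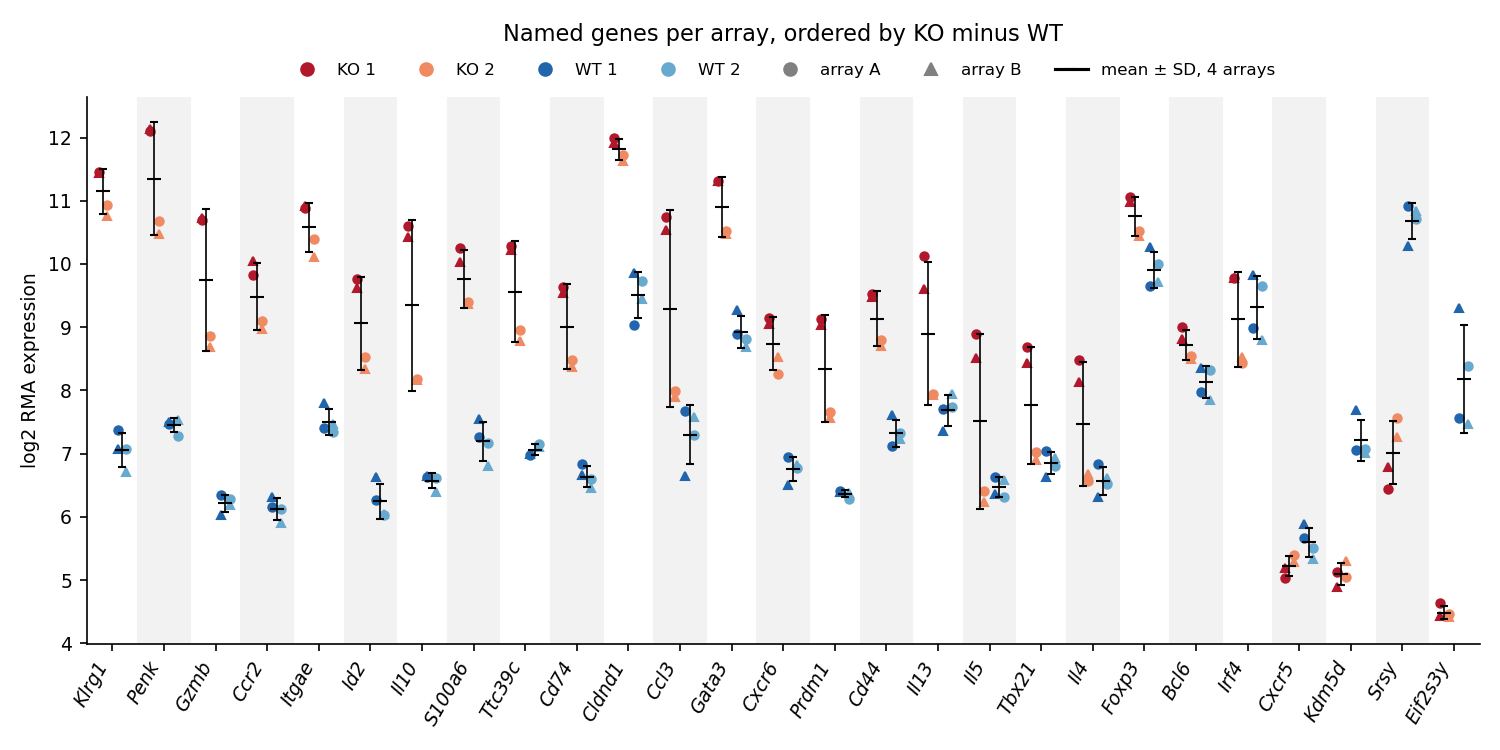
Log2 RMA expression of the 27 named genes in each array, ordered by the difference of the KO-labelled from the WT arrays; circles are array A, triangles array B, colours mark the preparation, and black bars the mean ± SD of 4 arrays. For Klrg1 the KO-labelled arrays have a mean of 11.15 against 7.06 in WT, while Il5 is at 8.89 and 8.51 in KO 1 and at 6.41 and 6.23 in KO 2, against 6.32 to 6.62 in WT.

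**Figure D3:**
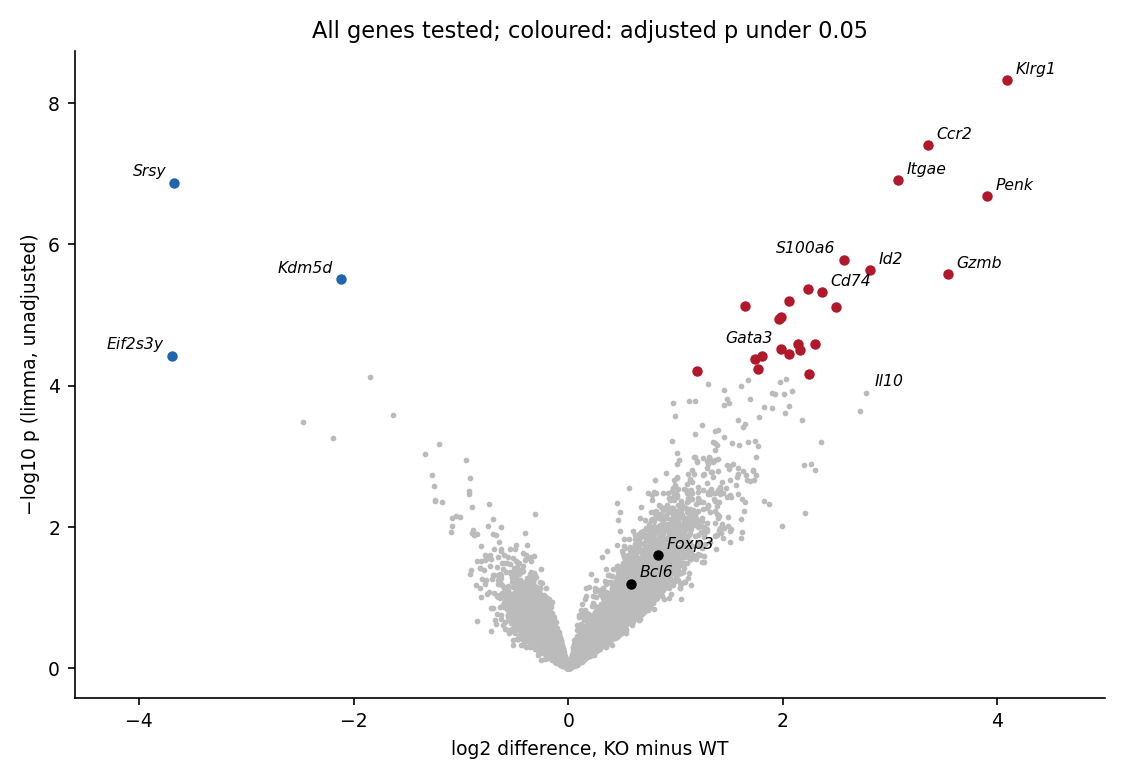
Log2 difference (KO-labelled minus WT) of each of the 19937 genes against the negative log10 of its unadjusted limma p. Red points are the 24 genes called higher, blue points the 3 called lower, and black points Bcl6 and Foxp3, which did not pass.

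Genes of effector Tregs had the highest median difference of the lists tested. Of 21 measured members, 6 rose over all genes tested (Klrg1, Gzmb, Ccr2, Itgae, Cd44 and Fgl2), 0 fell and 15 did not pass; 17 were higher adjusted over the list alone, and 14 over all genes after quantile normalization. Cd44, an adhesion receptor of activated T cells, was higher by 1.81 log2 (SE 0.29, adjusted p = 0.0328). Il10, an anti-inflammatory cytokine, had a log2 difference of 2.77 (SE 0.51, adjusted p = 0.0676) and Prdm1, which encodes the repressor Blimp-1, of 1.98 (SE 0.35, adjusted p = 0.0564), with all 4 KO-labelled arrays above all 4 WT arrays for each. The median member differed by 1.81, with 2.25 in preparation KO 1, the one with the wide spread of values, and 1.24 in KO 2. The set test with a preset correlation gave an adjusted p of 3.9e-61, and the call was lost with an estimated correlation (adjusted p = 0.249). The list passed in fry with the block (adjusted p = 0.0219). The Cd44 call was lost without KO 1B (adjusted p = 0.0767), WT 2A (adjusted p = 0.100), WT 2B (adjusted p = 0.0981) or both WT 1 arrays (adjusted p = 0.355), and with median centring (adjusted p = 0.164).

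The broader Treg signature list also passed the preset test (adjusted p = 3.7e-23), a call lost with an estimated correlation (adjusted p = 0.291) and in fry (adjusted p = 0.0946). Of its 27 measured genes, 2 rose (Itgae and Penk), 0 fell and 25 did not pass, and 12 were higher adjusted over the list alone; after quantile normalization 7 were higher and 1 lower over all genes. Foxp3 itself was 10.75 ± 0.31 in the KO-labelled and 9.91 ± 0.28 in the WT arrays (SD, n = 4 each), a log2 difference of 0.84 (SE 0.33) that did not pass (adjusted p = 0.701), although all 4 KO-labelled arrays were above all WT arrays. Other members past the threshold over the list alone, named here after their values were seen, included Entpd1, an ectonucleotidase, at 2.03 and Icos, a costimulatory receptor, at 1.93. The list median was 0.93, with 1.45 in KO 1 and 0.54 in KO 2.

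Among Th2 genes the transcription factor Gata3 rose, while the cytokine genes Il4, Il5 and Il13 did not pass the test. Gata3 (probe set 10479981), the factor that directs Th2 differentiation, was 10.90 ± 0.47 in the KO-labelled and 8.92 ± 0.25 in the WT arrays (SD, n = 4 each), a 3.96-fold rise with a log2 difference of 1.99 (SE 0.32, adjusted p = 0.0308). It was higher in both preparations, by 2.39 in KO 1 and 1.58 in KO 2. Of 16 measured list members, 1 rose, 0 fell and 15 did not pass, and 6 were higher adjusted over the list alone; 4 were higher over all genes after quantile normalization. Il4, Il5 and Il13 each had an adjusted p of 0.701. Their log2 differences from the WT mean were 1.74, 2.23 and 2.18 in KO 1 and 0.06, -0.15 and 0.25 in KO 2. Il10 was 3.95 above WT in KO 1 and 1.6 in KO 2. The list median was 0.97, with 1.62 in KO 1, whose arrays had the widest spread, and 0.19 in KO 2. The preset test gave an adjusted p of 1.1e-09, the estimated correlation an adjusted p of 0.18 and fry an adjusted p of 0.0233. The Gata3 call was lost without KO 1B (adjusted p = 0.0726), WT 2A (adjusted p = 0.088), WT 2B (adjusted p = 0.0934) or both WT 1 arrays (adjusted p = 0.166). Median centring (adjusted p = 0.196) and a block by letter (adjusted p = 0.0633) also ended it.

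Genes that BCL6 has been described to repress in lymphocytes were a separate list. Of 30 measured members, 3 rose (Id2, Gata3 and Cd44), 0 fell and 27 did not pass, and 10 were higher adjusted over the list alone; after quantile normalization 7 were higher over all genes and the median was 0.40. Ccl3, an inflammatory chemokine, had a log2 difference of 1.99 (SE 0.65, adjusted p = 0.561), with 3.34 in KO 1 and 0.64 in KO 2. Prdm1 was 2.72 above WT in KO 1 and 1.24 in KO 2. The T-box factor Tbx21, which directs Th1 differentiation, had a difference of 0.91 (SE 0.40, adjusted p = 0.701), with 1.71 in KO 1 and 0.11 in KO 2. The list median was 0.65, with 0.94 in KO 1 and 0.23 in KO 2. The preset test gave an adjusted p of 5.9e-14, the estimated correlation an adjusted p of 0.291 and fry an adjusted p of 0.0946.

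Receptors that guide T cells into tissues held 3 of the genes called higher. Of 23 measured chemokine receptors and homing genes, 3 rose (Ccr2, Itgae and Cxcr6), 0 fell and 20 did not pass; 11 were higher and 1 lower adjusted over the list alone, and 7 and 1 over all genes after quantile normalization. Cxcr6, the receptor of Cxcl16, rose by 1.98 log2 (SE 0.28, adjusted p = 0.014), with 2.34 in KO 1 and 1.63 in KO 2, and its adjusted p was 0.0506 without WT 2A and 0.295 without both WT 1 arrays. The list median was 0.64, with 0.66 in KO 1 and 0.60 in KO 2. The preset test gave an adjusted p of 9.4e-15, the estimated correlation an adjusted p of 0.18 and fry an adjusted p of 0.0233. Of 16 chemokine ligands limma called 0, with 2 higher at an unadjusted p under 0.05, 0 adjusted over the list alone and an adjusted p of 0.32 for the set, which became 0.036 without WT 1A.

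**Figure D4:**
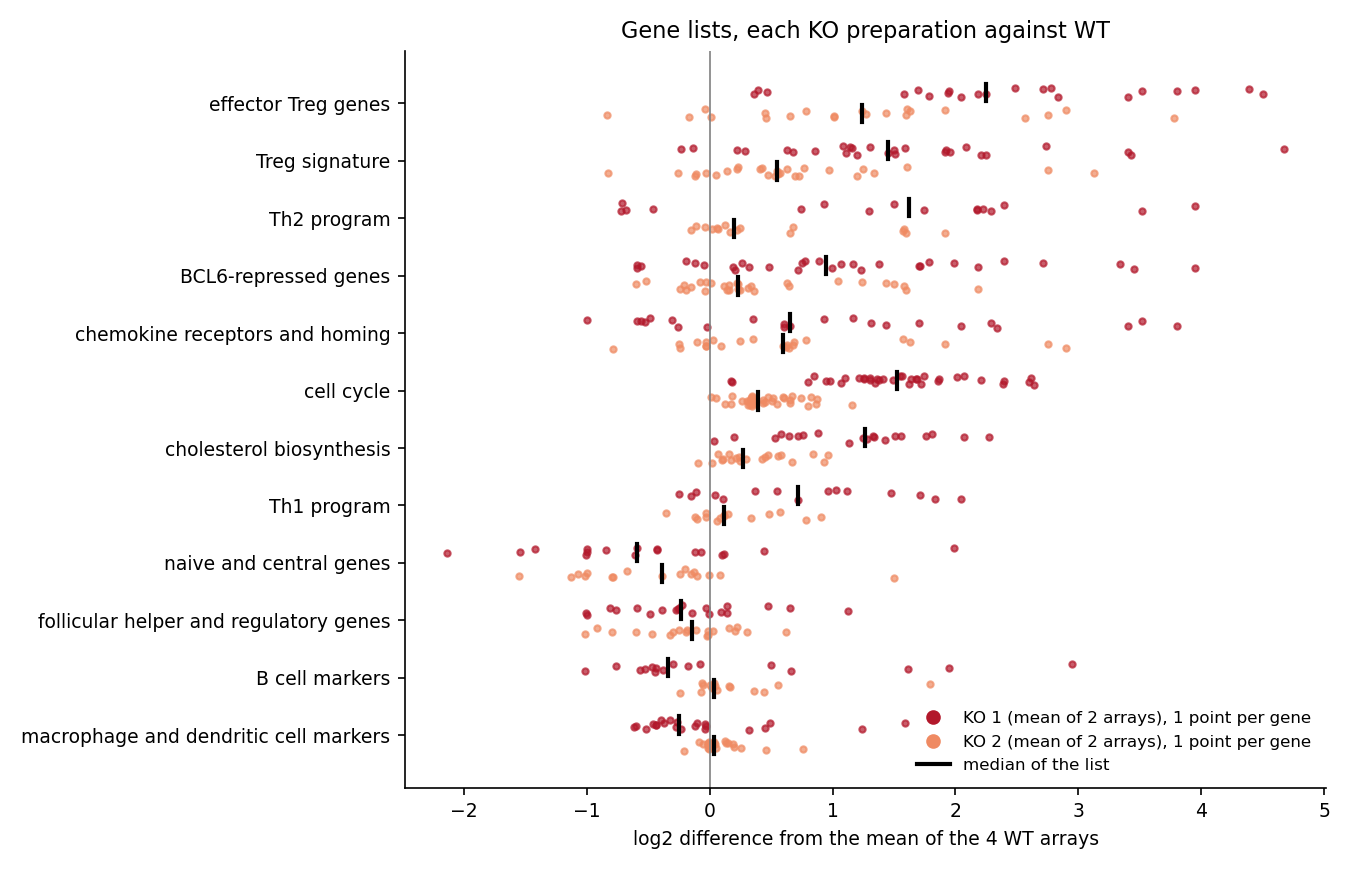
Log2 difference of each list member from the mean of the 4 WT arrays, with preparation KO 1 in red and KO 2 in orange, 1 point per gene; black bars are list medians. The median of effector Treg genes is 2.25 in KO 1 and 1.24 in KO 2, that of Th2 genes 1.62 and 0.19, and that of cell cycle genes 1.52 and 0.39.

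Genes of naive and central T cells had a median below 0. Of 17 measured members, 0 rose, 0 fell and 17 did not pass over all genes, with 1 higher and 7 lower at an unadjusted p under 0.05. Adjusted over the list alone, 6 were lower and 1 was higher. After quantile normalization 7 were lower and 1 higher over all genes, and the median was -0.72. Chosen after their values were seen, Actn1 was at -1.85 (SE 0.32), Foxp1, a factor of T cell quiescence, at -1.25 (SE 0.33) and Ccr7, the lymph node homing receptor, at -0.89 (SE 0.30). Il7r, the interleukin 7 receptor, was at 1.75 (SE 0.41). The list median was -0.42, with -0.59 in KO 1 and -0.38 in KO 2. The preset test gave an adjusted p of 3.0e-06 and the estimated correlation an adjusted p of 0.291. The follicular helper and regulatory list had 20 measured genes, of which limma called 0, with 2 lower at an unadjusted p under 0.05 and 0 adjusted over the list alone. Its median was -0.12, with an adjusted p of 0.0324 for a lower level in the preset test and an adjusted p of 0.392 with an estimated correlation. The preset call was also lost without KO 2B (adjusted p = 0.0844), WT 1B (adjusted p = 0.315) or WT 2A (adjusted p = 0.105), with array weights (0.140), with median centring (0.0670) and on ranks (0.105). It was 4.0e-04 after quantile normalization, where 2 members were lower over all genes, 2.3e-04 without WT 1A and 0.00281 without WT 2B. Cxcr5, the receptor that leads T cells to B cell follicles, was at -0.37 (SE 0.18, adjusted p = 0.701), with KO-labelled and WT arrays overlapping.

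The Th1 and Th17 lists held no member past the threshold over all genes, against 1 and 2 higher members after quantile normalization. Of 15 Th1 genes limma called 0, with 6 higher at an unadjusted p under 0.05 and 4 adjusted over the list alone; the median was 0.43, with 0.72 in KO 1 and 0.11 in KO 2. The preset test gave an adjusted p of 1.1e-04, the estimated correlation an adjusted p of 0.291, and the preset test with the SD of each array as a covariate, chosen after seeing the data, 0.0563. Of 14 Th17 genes limma called 0, with 4 higher both at an unadjusted p under 0.05 and adjusted over the list alone. Their median was -0.03 while their mean was 0.29 and the test pointed up, and the set did not pass (adjusted p = 0.0552). It passed towards higher levels without KO 1A (adjusted p = 0.0137), KO 1B (0.0438), WT 1A (0.0124) or WT 2B (0.0306), after quantile normalization (0.00619), and in further fits such as that without KO 1 (4.0e-08). Irf4, a factor induced by T cell receptor signalling, was at -0.18 (SE 0.49, adjusted p = 0.837), with 0.47 in KO 1 and -0.83 in KO 2.

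Proliferation and metabolism lists passed the preset test towards higher levels and did not pass with an estimated correlation (adjusted p = 0.291 for cell cycle, cholesterol synthesis and glycolysis genes and 0.384 for targets of interleukin 2 and STAT5). Limma called 0 of their members over all genes; after quantile normalization it called 3 cell cycle genes, 1 glycolysis gene and 4 interleukin 2 and STAT5 targets higher and 1 such target lower. All 36 measured cell cycle genes had a log2 difference above 0, and 30 were higher both at an unadjusted p under 0.05 and adjusted over the list alone. Their median was 0.94, with 1.52 in KO 1, the preparation of wide spread, and 0.39 in KO 2; the preset adjusted p was 1.3e-29. Named after their values were seen, Top2a and Mki67, markers of dividing cells, were at 1.78 (SE 0.36, adjusted p = 0.100) and 1.37 (SE 0.33, adjusted p = 0.253). All 20 cholesterol synthesis genes were above 0, with 13 at an unadjusted p under 0.05 and 8 adjusted over the list alone. Their median was 0.79, with 1.27 in KO 1 and 0.27 in KO 2, and a preset adjusted p of 5.5e-12. Targets of interleukin 2 and STAT5 (21 measured) had a median of 0.62, with 1.13 in KO 1 and 0.12 in KO 2, and glycolysis genes (19 measured) of 0.67, with 1.04 in KO 1 and 0.26 in KO 2. Adjusted over the list alone 7 and 1 were higher, and the preset adjusted p values were 4.4e-08 and 8.8e-08. With the SD of each array as a covariate, the preset call of the interleukin 2 and STAT5 list was lost (adjusted p = 0.0754).

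Lists of activation, stress and interferon genes passed the preset test with all arrays and did not pass with an estimated correlation (adjusted p = 0.534, 0.409 and 0.291). Early T cell receptor response genes (30 measured) had a median of 0.34, with 0.60 in KO 1, 0.06 in KO 2 and 0.11 after quantile normalization, and 1 higher adjusted over the list alone. Heat shock genes (15 measured) had a median of 0.61, with 0.94 in KO 1, 0.20 in KO 2 and 0.40 after quantile normalization, and type I interferon genes (25 measured) of 0.16, with 0.12 in KO 1 and 0.13 in KO 2, with 0 past the threshold over the list alone. On these 3 lists limma called 0 genes over all genes tested, with 9, 3 and 5 higher and 1, 0 and 0 lower at an unadjusted p under 0.05. After quantile normalization limma called 2 activation genes higher and 1 lower. The preset adjusted p values were 1.1e-05, 6.9e-04 and 0.00607. In the preset test the activation list was lost without KO 1 (adjusted p = 0.209) and with the SD covariate (0.927), heat shock genes without KO 1 (0.0936) and with the SD covariate (0.117), and interferon genes without WT 1B (0.0634). On the cytotoxic granule list, 1 of 15 genes rose (Gzmb) and 2 were higher adjusted over the list alone, with a preset adjusted p of 0.00199, an adjusted p of 0.249 with an estimated correlation and 0.0502 on ranks. Ribosomal protein genes (19 measured) had 0 called by limma, 0 at an unadjusted p under 0.05 and an adjusted p of 0.236, which became 0.0456 without WT 1B. The Y-linked list had 5 measured genes, of which 2 fell over all genes and 3 adjusted over the list alone, with a preset adjusted p of 1.1e-11 and an adjusted p of 0.159 with an estimated correlation.

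Markers of other cell types were measured on 10 lists with 105 entries, of which 1 rose and 0 fell, with 12 higher and 0 lower at an unadjusted p under 0.05. The gene that rose was Cd74, the invariant chain of MHC class II and a member of the B cell list, at 9.01 ± 0.67 against 6.64 ± 0.16 log2 (SD, n = 4 each), a 5.16-fold difference with an adjusted p of 0.00862. It was higher by 2.95 in KO 1 and 1.79 in KO 2. H2-Ab1, an MHC class II chain named after its values were seen, was at 1.25 (SE 0.34, adjusted p = 0.384) and passed over the list alone. On other marker lists, 1 eosinophil and 1 platelet marker were higher adjusted over the list alone. After quantile normalization 1 B cell and 1 eosinophil marker were higher over all genes. The eosinophil marker was Ccr3 in both cases, a chemokine receptor that is also on the Th2 and homing lists. It was at 1.25 with all arrays and at 1.57 in KO 2. Of the 7 measured eosinophil markers, 1 was above 0 with all arrays, namely Ccr3. List medians ranged from -0.29 for erythroid markers to 0.05 for neutrophil markers, and none of the 9 lists tested passed with all arrays. The B cell list, which holds Cd74, passed towards higher levels without KO 1 (adjusted p = 0.00399), with the SD covariate (0.0302) and over genes at log2 6 or above (0.0415). The eosinophil list, which holds Ccr3, passed towards higher levels without KO 1 (0.0174) and with the SD covariate (0.0302). Mast cell and basophil markers passed towards lower levels without WT 1B (0.0352). The erythroid list had 7 of 14 genes measured; 4 probe sets shared by several globin genes, outside these counts, were higher by 2.24 to 2.97 log2 and passed. With all arrays the adjusted p was 0.358 for B cell, 0.436 for plasma cell, 0.718 for macrophage and dendritic cell, 0.779 for neutrophil, 0.877 for eosinophil and 0.155 for mast cell and basophil markers. It was 0.509 for natural killer cell, 0.296 for erythroid and 0.575 for platelet markers. The CD8 T cell list had 2 measured genes, too few for the set test, and 0 called by limma. The B cell and plasma cell medians were below 0 while their means and tests pointed up, and the macrophage and eosinophil medians and tests pointed down while their means were above 0.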

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

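The test of sex as the sole source of the genes called higher was chosen only after the result was seen. Arrays that lay far from the other 3 of their group were sought in 56 groups of 4 values, and 2 were found, where chance finds about 1 in 20 groups. Kdm5d was 7.70 log2 in WT 1B and 7.02 to 7.07 in the other WT arrays. Il10 was 6.40 in WT 2B and 6.62 to 6.64 in the other WT arrays.

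Outside the genes of the main test, 6997 probe sets with no gene symbol or with several were fitted in the same model, and 14 passed the threshold, 7 higher and 7 lower in the KO-labelled arrays. Of those higher, 4 were shared by several globin genes, 2 by Hba-a1 and Hba-a2 and 2 by the Hbb genes, with differences of 2.24 to 2.97 log2, KO-labelled values of 9.22 to 11 and WT values of 7.16 to 7.97. The other 3 that were higher had no gene symbol; probe sets 10429564 and 10345791 both differed by 3.54. All 7 that were lower had no gene symbol, with probe set 10608138 at -3.64 and 10608579 at -3.23. Probe sets 10608041 and 10608062 held the same values in every array, so the 7 are not all separate measurements. The identifiers of the 7, from 10608041 to 10608600, run close to those of the Y-linked genes Eif2s3y (10608001) and Srsy (10608426). Their place in the genome was not used here, so whether they are Y-linked too was not tested. Other erythroid markers did not follow the globin probe sets, with 7 measured, 0 called by limma, 0 at an unadjusted p under 0.05 and a median of -0.29.

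The Y-linked genes Eif2s3y and Kdm5d fell by 3.69 and 2.12 log2 in the KO-labelled arrays. A candidate explanation is that the KO-labelled animals were female and the WT animals male. X-linked genes that escape inactivation had to lie higher then. Kdm6a was at 1.37, Kdm5c at 0.97, Eif2s3x at 0.96 and Ddx3x at 0.65, although none of the 4 passed the test. Their median was 0.969, and 0.710 after quantile normalization. Other genes rose alike, such as cell cycle genes, with a median of 0.94, and 0.76 after quantile normalization. The rise is therefore not particular to X-linked genes and does not by itself decide the sex of the animals. The mean of Eif2s3y, Kdm5d and Uty was 4.62 to 4.80 in the KO-labelled arrays, below the lower quartile of each of those arrays (5.79 to 6.16). In the WT arrays it was 6.95 to 8.30. Such levels go with female KO-labelled and male WT animals, while Usp9y and Zfy1 differed by only -0.105 and -0.045. The Y-linked level followed the genotype label in every array, with 0 arrays against it, so for the 24 genes called higher an effect of sex cannot be told apart from one of genotype. Leaving the Y-linked genes out left 21 genes higher and 0 lower, a setting that removes those genes and not other effects of sex.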

How the results depend on the processing

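The tests with the SD of each array as a covariate, without KO 1 or KO 2 and with no random block, without Y-linked genes, and with quantile normalization of preparation means were chosen after seeing the data. All 27 called genes that were tested kept their direction in all 32 alternatives, and at least 20 of them also stayed past the threshold in 23 of these. The KO-labelled and WT arrays of these genes do not overlap. Leaving out arrays, or changing the block, the variance model or the weights, could therefore not turn their direction. The counts moved more, from 24 higher and 3 lower genes to 45 and 7 with the mean of A and B per preparation, 92 and 21 with no random block, 61 and 5 with array weights, and 121 and 36 with quantile normalization. Median centring gave 12 higher genes, a test against a 1.2-fold change 14, and every probe set 11 lower ones, since more probe sets were tested. Leaving out 1 array gave 13 to 51 higher and 2 to 6 lower genes. Without both arrays of WT 1 there were 8 higher genes, and without both of WT 2 there were 0 higher and 0 lower by limma, with 200 at an unadjusted p under 0.05. Without KO 1 there were 1124 and 341, and without KO 2 7234 and 9666, in fits whose estimated correlation between arrays was -0.63 and -0.64; with no random block these became 128 and 16, and 5997 and 7381. The SD covariate gave 1599 and 884, with an estimated correlation of -0.37. Leaving out Y-linked genes gave 0 lower genes by construction, and quantile normalization of preparation means gave 4 higher genes, with 6 of the 27 called. Apart from the smaller number of arrays and the settings said to act by construction, the cause was not tested.

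The labels do not say whether the numbers 1 and 2 pair the samples across groups, and the values do not decide it. The differences KO 1 minus KO 2 and WT 1 minus WT 2 had a correlation of 0.416 over genes, from 2 pairs only, and arrays of the same number and letter had correlations of their deviations of -0.691, 0.771, -0.42 and 0.682. The replicate block gave 111 higher and 9 lower genes, the block by letter 14 and 2, with 16 of the 27 called. Among named genes, the block by letter ended the limma calls of Gata3 (adjusted p = 0.0633), Cd44 (0.0637), Cldnd1 and Eif2s3y (0.0518 each). The block by number and letter gave 98 and 15, and the block on preparation means 121 and 11.

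Bcl6 stayed above 0 in all 32 alternatives, at 0.34 to 0.78 log2 with adjusted p of 8.3e-06 to 1, and passed in 4: 0.34 with the SD covariate, 0.40 without KO 1, and 0.78 without KO 2 with or without the random block. The KO-labelled and WT arrays of Bcl6 do not overlap either, so most of these settings could not turn its sign. The preset list tests called 13 to 16 lists higher and 2 to 3 lower in the other alternatives, but not always the same lists. Without KO 1, T cell receptor activation (adjusted p = 0.209) and heat shock genes (0.0936) were lost and Th17 genes (4.0e-08), B cell (0.00399) and eosinophil markers (0.0174) gained. With the SD covariate, Th1 (0.0563), interleukin 2 and STAT5 (0.0754), activation (0.927) and heat shock genes (0.117) were lost and Th17 genes (8.7e-07), B cell and eosinophil markers (0.0302 each) gained. Neutrophil markers passed in quantile normalization of preparation means (0.0454). Set tests of another kind differed more: camera with an estimated correlation gave 0 and 0, and fry 3 and 1. Signs reversed for Il5, which did not pass, at -0.15 with the SD covariate (adjusted p = 0.737) and -0.15 without KO 1 with or without the block. Irf4, at -0.18 with all arrays, ranged from -0.39 to 0.019 when 1 array was left out, with 0.019 without WT 1B, 0.00068 without WT 2A and 0.47 without KO 2 with or without the block. The median of eosinophil markers went from -0.19 to 0.095 with the SD covariate and 0.050 without KO 1 with or without the block. In these settings the medians of Th17 genes and of B cell (0.07 and 0.04), plasma cell (0.12 and 0.11), macrophage and dendritic cell (0.05 and 0.04), mast cell (0.13 and 0.08), platelet (0.11 and 0.06) and CD8 T cell markers also turned from below to above 0, and with the SD covariate that of natural killer cell markers (0.02). With the SD covariate more list members passed, such as 24 cell cycle genes, 17 higher and 2 lower Treg signature genes, and 1 higher and 8 lower follicular genes. Quantile normalization also turned the medians of Th17 genes (0.08), plasma cell (0.06) and macrophage and dendritic cell markers (0.01). Signal over background is unknown in these summaries, so dim genes were kept; a filter at log2 6 gave 25 higher and 3 lower genes.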

Other observations

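The tests on the spread of values and on FoxP3 cell content below were chosen only after the results were seen; the tests on B cells, macrophages, mast cells, splits of the arrays and genes around Bcl6 were not, though their values in KO 2 alone and after quantile normalization, given for B cell and macrophage markers, were added later. Another 11 called genes fall outside the naming rule and were chosen after their values were seen. All were higher in the KO-labelled arrays, with no overlap with WT. Tnfsf10, the death ligand TRAIL, differed by 2.25 log2, Car5b, a mitochondrial carbonic anhydrase, by 2.24, Il1r2, the decoy receptor of interleukin 1, by 2.16 and Cd200r1, an inhibitory receptor, by 2.14. Fgl2, a secreted product of effector Tregs, differed by 2.06, Cpd by 2.05, Lamc1, a laminin chain, by 1.96, Atp6v0d2 by 1.77, Cpox, an enzyme of heme synthesis, by 1.74, Neb by 1.65 and S100a4 by 1.2. Of these 11, Atp6v0d2 and S100a4 lay higher in KO 2 than in KO 1, at 2.11 and 1.25 against 1.44 and 1.15 above the WT mean, while without KO 1 the difference was 1.47 for Tnfsf10 and 1.54 for Cd200r1. Of the 32 alternatives, Tnfsf10 passed in 17, Atp6v0d2 in 18, S100a4 in 19, Cpox in 21, Il1r2 and Cd200r1 in 22, Fgl2 in 23, Lamc1 in 27, Cpd and Neb in 28 and Car5b in 29. Leaving out both arrays of WT 1 ended all 11 calls (adjusted p = 0.0807 to 0.973), and so did leaving out those of WT 2 (0.665 to 0.999). Tnfsf10, Atp6v0d2, S100a4, Cpox, Il1r2 and Cd200r1 also failed without KO 1B (0.0637 to 0.132), WT 2A (0.0662 to 0.156) or WT 2B (0.0805 to 0.140), Fgl2 without KO 1B (0.0689) or WT 2B (0.0805), Lamc1 without WT 2B (0.0504) and Neb without WT 2A (0.0506). Leaving out KO 2A ended the calls of Tnfsf10 (0.0770), Atp6v0d2 (0.0607) and Cpox (0.0647), WT 1A those of S100a4 (0.193), Atp6v0d2 (0.0799) and Cpox (0.0642), KO 1A that of Tnfsf10 (0.0654) and WT 1B that of S100a4 (0.086). On preparation means the adjusted p of S100a4 was 0.137.

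Genes called higher could follow the wider spread of values in KO 1, or other cells in the sorted gate. The spread as sole cause is argued against by quantile normalization, which gives all arrays 1 spread: 24 of the 24 genes stayed past the threshold, with a median difference of 2.07 log2 (median SE 0.20) against 2.20 (median SE 0.31) as deposited, and on preparation means as well the median stayed at 2.07 (median SE 0.21) while 4 passed, in a fit with 5.47 degrees of freedom in place of 10.3. B cells are argued against by 7 B cell markers other than Cd74, with a median of -0.12, 0.02 after quantile normalization and at most 0.17 in KO 2. Macrophages and dendritic cells are argued against by 22 markers, with a median of -0.12, 0.01 after quantile normalization and 0.04 in KO 2. The highest of the 22 in KO 2 was Cst3 at 0.76. None of the 7 and 22 markers passed as deposited or after quantile normalization, with Cd79b at 0.33, Lyz2 and Cd68 at 0.35, Ctss at 0.85 and Cst3 at 1.18. The 7 markers leave out the MHC class II genes of the B cell list, such as H2-Ab1, which passed over that list alone. Of its 16 measured members, 4 were higher and 0 lower at an unadjusted limma p under 0.05, Cd74 among them. The rise of Cd74 and H2-Ab1 is not explained by these tests. The 4 globin probe sets that were higher leave red cell RNA as an open source for themselves. The 7 measured genes of the erythroid list did not follow them, with a median of -0.29 and 0 called by limma. Red cell RNA was not tested further. An effect of sex stays open, as 0 arrays had a Y-linked level that went against the genotype label.

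Cytokine and effector genes were far higher in KO 1 than in KO 2, a difference with no replicate of its own and not tested. After quantile normalization the median KO 1 minus KO 2 difference of Il4, Il5, Il13, Il10, Gzmb and Ccl3 was 1.76, from 1.51 for Il13 to 2.34 for Ccl3, which argues against spread as the sole cause. Mast cells or basophils, which also make Il4 and Il13, are argued against by a median of -0.097 over their markers. Fewer FoxP3 cells in KO 1 stay open: the median of Foxp3 (0.21), Il2ra (1.21), Ikzf2 (-0.06), Ctla4 (0.63) and Tnfrsf18 (0.78) was 0.63, but 4 of 27 Treg signature genes lay lower in KO 1, with Nrp1 at -0.54 and Izumo1r at -0.14, and genes this high could hide a small share of other T cells. Activation, mouse and stage differences between the preparations stay open too, as the labels do not describe them.

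In 2 of the 35 splits of the 8 arrays into 4 and 4, limma called at least as many genes as the 27 of the real split, so chance is not excluded by this count. The other split set KO 1A, KO 1B, WT 1B and WT 2A against the rest and called 6860 genes, which points to a structure of the samples. Those arrays are 4 of the 5 with the widest spread of values. Of the 3 splits that keep preparations whole, 1 gave as many genes, the real one, and the highest other called 0; 3 splits are too few for a share under 0.05. Arrays WT 1A and WT 2B correlated at 0.994 over probe sets and WT 1A and WT 1B at 0.968, while KO 1A with KO 1B and KO 2A with KO 2B reached 0.995.

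It was also asked whether genes around Bcl6 changed together, as DNA of another mouse strain left around the targeted locus might cause. Of the 100 named genes nearest to Bcl6, 50 on each side, 7 had an unadjusted p under 0.05, against a mean of 6.21 in random runs of neighbouring genes (permutation p = 0.414, one-sided, over genes), and limma called 0 after adjustment. These values show no excess, though a few genes could still differ there.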
